A study of Mus musculus with 9 samples.

How the data were processed

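Gene expression was measured in 9 RNA-seq libraries of bone-marrow-derived macrophages from C57BL/6 mice, 3 each of untreated cells (control), cells given LPS (500 ng/ml, 6 h) and cells given LPS with the PHGDH inhibitor NCT503 (50 µM, 6 h). Per the submitters' processing notes, reads were aligned with TopHat2 to the mouse genome mm10, and the program versions, the read counter, the gene annotation, the strand setting and the differential test are not given in the sources used here. The authors deposited a table for LPS against control (23001 genes) and one for LPS with NCT503 against LPS (22620 genes), 24187 genes in all. Per the file headers and the values, each table holds signal per library, which is the number of reads per gene divided by a size factor, and the group means of that signal. Each table also holds the authors' comparison, with the log2 fold change in log2 units and the p-value and its adjusted form in p-value units. Of the 24187 identifiers 24141 (99.8%) are in GENCODE M21, 92.6% of these with the same start and end, and 38 identifiers share a symbol with another, so that Aldoa counts as 2 members of the glycolysis list.

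The signal was checked for whole reads. In each of the 12 library columns 100% of values were whole multiples of the smallest value (tolerance 0.001), and the recovered size factors equal the DESeq2 median-of-ratios factors of its 6 libraries. The LPS libraries, which are in both tables, gave the same reads in 100% of values over 21434 shared genes, so the 9 libraries were joined and normalized together for the comparison of LPS with NCT503 against control. The unit therefore differed from those foreseen in the plan (counts, or FPKM, RPKM or TPM). The plan for FPKM, RPKM or TPM was used for the tests, with its minimum mean of 1 applied to normalized reads. The test planned for counts, edgeR with its standard filter, was run on the recovered reads as an added alternative. Over the 21434 shared genes, library totals were 20295862 to 23599685 reads. Size factors over the 9 libraries were 1.25 to 1.46 in control, 0.733 to 0.868 in LPS and 0.924 to 0.981 in LPS with NCT503. Of the shared genes 19351 ± 552, 18550 ± 436 and 19164 ± 239 had at least 1 read. Genes in 1 table only had at most 1 read in any LPS library. They are left out of these counts and of the comparison of LPS with NCT503 against control. Over all genes of a table, 19516 to 20933 had a read in control, 18252 to 19218 in LPS and 19505 to 20074 in LPS with NCT503. The 100 most abundant genes took 30.1 ± 1.56%, 31.8 ± 1.56% and 31.1 ± 0.886% of reads.

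The comparisons, the tests, the 35 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Each comparison used the 3 libraries of either group. Genes with a mean of at least 1 normalized read in one group were tested with limma-trend (limma 3.58.1 in R 4.3.3, eBayes with trend and robust) on log2(normalized reads + 1), and those with a Benjamini-Hochberg adjusted p under 0.05 were called. The fold change is that of log2(value + 1) and understates the change of genes with few reads. The labels do not say that replicates are separate cultures or animals, so p-values measure the spread between these libraries alone. Replicate numbers were not used as pairs. Gene lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the 35 lists), with camera under an estimated correlation and fry beside it, where fry tests whether the genes of a list move one way on balance and does not compare them with other genes. The overlap of the first 2 comparisons was set against 20 simulations in which no gene differed, and repeated with no LPS library in both (a group of 1 library takes its variance from the other group, and the size factors stayed those of all libraries).

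Genes named in the text follow a rule. They are the 6 largest rises and 6 largest falls among called genes whose groups do not overlap in any library, with at least 10 CPM in the higher group and leaving out provisional names. They include 12 genes whatever their values (Phgdh, Psat1, Psph, Shmt2, Mthfd2, Il1b, Il6, Tnf, Ifnb1, Il10, Nos2, Arg1), and up to 4 members of each list with the smallest p. The others were chosen after their values were seen: Tlr4, Gpx1 and Ccne1 with LPS, Farsa, Wars, Insig1, Ptgs2, Cxcl1, Tnfsf15, Csf1, Nlrp1b, Ticam1, Traf3 and Traf6 with NCT503, Cxcl2 in the overlap, and those given under other observations. The exons of 30 of the 126 genes named in the results overlap exons of another gene in GENCODE M21, among them Dbp (Sphk2), Samd11 (Noc2l), Cyp51 (Akap9), Fdft1 (Ctsb), Cxcl10 (Art3), Myd88 (Acaa1a), Psph (Cct6a), Mars (Ddit3) and Prtn3 (Plppr3), and since the strand setting is not given their values are uncertain where such reads were shared.

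Sensitivity to the processing was tested with a pseudocount of 0.1, no filter, TMM scaling, quantile normalization, a log2 fold change of at least 1, all 9 libraries in 1 fit, the replicate number as a block, each library left out in turn, edgeR 4.0.16 quasi-likelihood without a filter and with at least 10 CPM in every library of a group, DESeq2 1.42.0, limma-voom and the authors' deposited fold changes. Alternatives chosen after seeing the data were edgeR with its standard filter on the recovered reads, a mean of at least 10 normalized reads, CPM (scaling to library totals), leaving out control 1 and LPS_NCT503 2 together, and different LPS libraries in the first 2 comparisons. The edgeR fit called 7769 of 13739 genes with LPS against control, 6087 of 13300 with LPS and NCT503 against LPS and 7546 of 14086 with LPS and NCT503 against control. The whole procedure was tested on simulated data with known changes and the same depths: it recovered 57%, 45% and 44% of 2-fold changes and 92%, 92% and 91% of 4-fold changes in the 3 comparisons, with 10, 13 and 12 false calls among 19594, 19559 and 19831 genes and 0 lists called. The changed genes, 100 per fold, had a mean of at least 10 normalized reads, so recovery below that was not measured. Genes were drawn independently and far fewer changed than in the data. The 0 lists therefore do not show how often correlated genes give false list calls. Near-identical gene copies were searched with BLAST+ 2.17.0 and seqkit 2.13.0 (at least 95% identity over 80% of the length), tables were handled with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9.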

Results

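Macrophages differentiated from mouse bone marrow were compared in 3 states: untreated, stimulated with the bacterial cell wall component lipopolysaccharide (LPS) for 6 h, or stimulated with LPS for 6 h in the presence of NCT503, a small molecule that inhibits phosphoglycerate dehydrogenase (PHGDH), the enzyme that commits glycolytic carbon to serine synthesis. Each state had 3 RNA-seq libraries of 20295862 to 23599685 assigned reads over the 21434 genes shared by both deposited comparisons. The comparisons address how LPS changes the macrophage transcriptome, which of these changes differ when the inhibitor is present, and what remains of the response relative to untreated cells. Values are size-factor-normalized reads (mean ± SD, n = 3 libraries per group) and log2 fold changes ± SE. Genes said to rise or fall passed an adjusted p of 0.05 in limma, and for the genes of largest change every library of one group lay above every library of the other.

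LPS induced genes of acute inflammation, some of them by more than 3 orders of magnitude. Il1b (chromosome 2, 129364570 to 129371139), the precursor of a fever-inducing cytokine, rose from 16.1 ± 5.10 to 47489 ± 4753 normalized reads, a log2 fold change of 11.48 ± 0.21 (adjusted p = 5.10e-11). Nos2, the inducible nitric oxide synthase, rose by 11.47 ± 0.39 on the log2 scale, from 17.6 ± 10.98 to 49295 ± 18403. Csf3, a granulocyte growth factor, had 7481 reads in the LPS libraries and 2 in the control libraries, all in control 1. Scaled by the size factors, the ratio was 6576 (95% counting interval 1820 to 54308, which leaves out the spread between libraries). Ptgs2, the inducible cyclooxygenase (9.82 ± 0.39), the chemokine Cxcl10 (9.66 ± 0.26) and the uridine phosphorylase Upp1 (9.59 ± 0.26) completed the 6 largest rises. The largest falls were those of Arhgap19, a GTPase-activating protein, from 5752 ± 335 to 84.8 ± 8.87 (log2 −6.07 ± 0.15), Nat8l (−5.91 ± 0.37), the sialyltransferase St6gal1 (−5.65 ± 0.20), the circadian transcription factor Dbp (−5.55 ± 0.28), the palmitoyltransferase Zdhhc14 (−5.54 ± 0.21) and the ubiquitin ligase Rnf144b (−5.50 ± 0.18).

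Among the genes named before the data were examined, Phgdh, the target of the inhibitor, rose with LPS from 212 ± 26.6 to 454 ± 149 normalized reads (log2 1.05 ± 0.23, adjusted p = 0.00327). Psat1, which encodes the next enzyme of serine synthesis, rose by 1.04 ± 0.19 (adjusted p = 0.00108) and the mitochondrial folate enzyme Mthfd2 by 0.80 ± 0.15 (adjusted p = 0.00126). Psph, the last enzyme of the pathway (−0.08 ± 0.21, adjusted p = 0.776), and Shmt2, which passes the carbon of serine to folate (−0.24 ± 0.21, adjusted p = 0.376), did not pass the test. These calls depend on the scaling: under CPM scaling (library totals alone) the 3 rises were 0.35, 0.34 and 0.09 and none passed, whereas Psph (−0.78) and Shmt2 (−0.94) did. Il6 (9.43 ± 0.30), Tnf (7.96 ± 0.18), Ifnb1 (2.32 ± 0.44) and the anti-inflammatory cytokine Il10 (3.60 ± 0.17) rose as well, and Arg1, at 7.17 ± 4.14 against 3.33 ± 2.39 reads, did not pass (0.99 ± 0.61, adjusted p = 0.221).

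**Figure D1:**
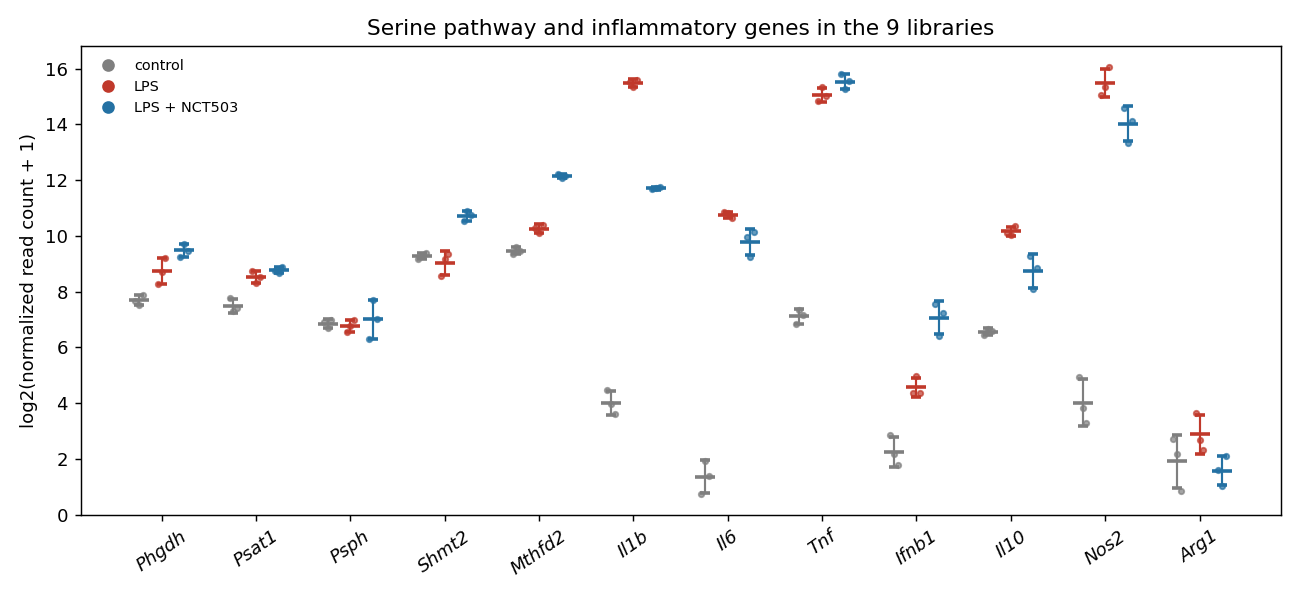
Expression of the 12 genes named before the data were examined, in log2(normalized reads + 1), with 1 point per library and a bar at the mean ± SD of the 3 libraries of each group. Il1b, Nos2, Il6 and Tnf are high in each LPS library, and with NCT503 Il1b is lower and Ifnb1, Shmt2 and Mthfd2 are higher than with LPS alone.

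Inflammatory, interferon and Toll-like receptor gene lists were called higher with LPS. Unless another count is given, as many members passed when adjusted over the list alone. All 22 feedback regulators of Toll-like receptor signalling rose (median log2 4.31, adjusted p = 1.07e-22), among them Socs3 (8.93), Traf1 (5.67), Nfkbia (5.46) and Tnfaip3 (5.20), which restrain cytokine and NF-κB signalling. All 31 genes of type I interferon and its targets rose (median 3.01, adjusted p = 5.06e-22, and adjusted p = 0.137 with an estimated correlation). Among these were Gbp5 (6.96), Cmpk2 (5.63) and Isg15 (5.02). Of the chemokines 16 of 17 rose (median 5.46, adjusted p = 1.76e-16), led by Cxcl10, which attracts T cells, Cxcl11 (8.58, annotated as a polymorphic pseudogene) and Ccl22 (6.19). Of the inflammatory cytokines 16 of 17 rose (median 5.53, adjusted p = 2.76e-16), including Il27 (7.76) and Il1a (7.54). Of the antimicrobial and prostanoid effectors 14 of 15 rose (median 4.01, adjusted p = 3.36e-14), including the prostaglandin synthase Ptges (9.38), the itaconate enzyme Acod1 (8.49) and the iron-scavenging Lcn2 (5.08). Of the Toll-like receptor pathway components 15 of 21 rose, 16 adjusted over the list alone, with Cd14 (4.39) and Tlr2 (3.18), while Tlr4, the LPS receptor itself, fell (median 1.24, adjusted p = 5.37e-07).

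Antigen presentation, inflammasome, heat shock, NRF2 and ATF4 target lists were also called higher, of which the class II, inflammasome and heat shock medians turn sign under another scaling. Of 15 class I antigen presentation genes 14 rose (median 1.70, adjusted p = 2.74e-08, and adjusted p = 0.239 with an estimated correlation). They included the proteasome activator Psme2 (3.26) and the peptide transporter Tap2 (2.57). Of 12 class II and costimulation genes 9 rose, 10 with 1 lower adjusted over the list alone, although their median of 0.83 turns to −0.06 under quantile normalization (adjusted p = 0.000492, and adjusted p = 0.2397 with an estimated correlation). They were led by the costimulatory receptor Cd40 (6.34) and the checkpoint ligand Cd274 (3.75). Of 12 inflammasome components 6 rose and 1 fell, 7 and 2 adjusted over the list alone, although the median of 0.66 turns to −0.04 under CPM scaling (adjusted p = 0.0378, and adjusted p = 0.220 with an estimated correlation). Nlrp3 (5.34) and Casp4 (3.77) rose and Nlrp1b (−5.13) fell, and the call is lost without LPS 1 (adjusted p = 0.0517) or LPS 3 (0.0585), with a range of 0.000168 to 0.220 over 14 alternatives. Of 15 cytosolic heat shock genes 7 rose, although their median of 0.62 turns to −0.08 under CPM scaling (adjusted p = 0.000572, and adjusted p = 0.138 with an estimated correlation). Examples are the near-identical and therefore uncertain pair Hspa1a (4.69) and Hspa1b (4.64). Of 26 NRF2 targets and glutathione genes 14 rose and 1, Gpx1, fell (median 0.82, adjusted p = 0.000326, and adjusted p = 0.487 with an estimated correlation). The reductases Gsr (2.87) and Txnrd1 (2.35) rose. Of 25 ATF4 targets of the amino acid response 15 rose and 2 fell (median 1.06, adjusted p = 0.000388, and adjusted p = 0.2397 with an estimated correlation). The cystine transporter Slc7a11 (4.37) and the stress phosphatase subunit Ppp1r15a (3.21) rose.

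Metabolic and proliferative genes moved in different directions. Of 30 genes of glycolysis and HIF1A targets 24 rose and 2 fell, 25 and 2 adjusted over the list alone (median 1.35, adjusted p = 1.61e-08, and adjusted p = 0.143 with an estimated correlation). The glucose transporter Slc2a1 (3.92), the lactate exporter Slc16a3 (3.29) and the glycolytic activator Pfkfb3 (3.15) rose. Of 24 cholesterol synthesis genes 18 rose and 1 fell, 19 and 1 adjusted over the list alone (median 1.19, adjusted p = 5.18e-07). The squalene synthase Fdft1 (2.11) rose and Dhcr7, the last step of the pathway, fell (−1.95). In the tricarboxylic acid cycle 9 of 23 genes fell and 2 rose, with 10 lower and 3 higher adjusted over the list alone (median −0.38, adjusted p = 0.0378, and adjusted p = 0.617 with an estimated correlation). The isocitrate dehydrogenases Idh1 (−2.74) and Idh2 (−1.94) fell, and the call of the cycle is lost without control 3 (adjusted p = 0.128), LPS 1 (0.0510) or LPS 3 (0.0585), with a range of 4.96e-05 to 0.617 over 14 alternatives. Of 30 cell cycle genes 28 fell (median −1.42, adjusted p = 2.82e-09, and adjusted p = 0.237 with an estimated correlation). These included the spindle checkpoint kinase Bub1b (−2.40) and Ccnd1 (−2.63), while Ccne1 rose. Of 23 p53 targets and apoptosis genes 15 rose and 6 fell (median 1.13, adjusted p = 0.00888, and adjusted p = 0.143 with an estimated correlation). The survival gene Bcl2a1b (3.62, uncertain because of near-identical copies) rose and the stress sensor Sesn1 (−5.36) fell.

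The serine synthesis and one-carbon metabolism list as a whole was not called with LPS: 7 of 24 genes rose and 8 fell, 7 and 9 adjusted over the list alone (median −0.16, adjusted p = 0.959). The methionine synthase Mtr (−3.03) fell. Macrophage identity genes, 7 of 18 higher and 3 lower (9 and 3 adjusted over the list alone), had an adjusted p of 0.0620, which becomes 0.0284 without LPS 1, 0.0382 without control 3 and 0.0376 without a filter on low values, within a range of 0.00352 to 0.652 over 14 alternatives. Chaperones of the endoplasmic reticulum, 9 of 20 higher and 2 lower (10 and 2 adjusted over the list alone), also had 0.0620, and 0.0366 without LPS 2, 0.0479 without control 3 or 0.0376 without the filter (range 0.00612 to 0.917). For the respiratory chain, 6 of 30 were higher and 2 lower, 6 and 1 adjusted over the list alone (adjusted p = 0.278, and 0.0382 without control 3, range 0.0382 to 0.992). The remaining lists not called were ribosome biogenesis (5 of 20 higher, 6 lower, adjusted p = 0.729), cytosolic aminoacyl-tRNA synthetases (6 of 20 and 8, or 7 and 9 adjusted over the list alone, 0.959), fatty acid metabolism (6 of 25 and 7, or 7 and 8 adjusted over the list alone), lysosome (7 of 32 and 7, called lower under CPM scaling with an adjusted p of 0.0103, range 0.0103 to 0.992), alternative activation (4 of 13 and 4), and histone methylation (5 of 18 and 6, or 6 and 6 adjusted over the list alone), these last 4 at 0.983. The median, mean and test differ in sign in 7 lists at 0.983: fatty acid metabolism (−0.08, 0.06, lower), lysosome (0.06, −0.03, higher), alternative activation (−0.19, 0.01, lower), histone methylation (0.05, 0.01, lower), dendritic cell markers (−0.04, 0.32, higher), neutrophil markers (0.05, −0.08, lower) and erythroid markers (−0.21, 0.05, lower).

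Markers of other cell types were measured beside these groups. Of 12 fibroblast and stromal markers 5 rose with LPS (median 1.21, adjusted p = 0.0108, and adjusted p = 0.617 with an estimated correlation). These included Thy1 (2.02). Relative to their mean over all libraries, the median stromal marker stood at −1.76 and −1.13 in controls 2 and 3 but at 0.39 in control 1, and between −0.05 and 1.15 in the other 6 libraries. Mast cell and basophil markers (4 of 8 higher, adjusted p = 0.0620, and 0.0284 without LPS 1, 0.0363 without control 2 or 0.0376 without the filter, range 0.0120 to 0.529), osteoclast markers (4 of 9 higher, 1 lower, 0.130) and T and natural killer cell markers (3 of 12 higher, 1 lower, 2 and 1 adjusted over the list alone, 0.519) were not called. At an adjusted p of 0.983 were dendritic cell markers (2 of 8 higher, 2 lower), neutrophil and granulocyte markers (3 of 14 higher, 4 lower), B cell markers (1 of 6 higher, 1 lower) and erythroid markers (0 of 4).

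Across all genes tested with LPS against control, 8355 of 19975 passed, 4089 higher and 4266 lower, and 5711 of them changed at least 2-fold. The authors' deposited comparison passes 7786 genes (3984 higher, 3802 lower) at the same adjusted p. The balance of rises and falls rests on the scaling: under CPM scaling, which shifts the median of all genes by −0.63, 2092 rose and 8536 fell, while TMM and quantile normalization shift it by −0.09 and −0.05. Of the 35 lists 18 were called, 16 higher and 2 lower, and of these the Toll-like receptor feedback and pathway, chemokine, cytokine, effector and cholesterol synthesis lists also pass with an estimated correlation. Other groupings of the same 6 libraries called up to 17 lists. Those groupings mix the treatments unevenly and keep part of the treatment difference, so they do not measure chance calls.

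Adding NCT503 to LPS raised Rasd2, a small GTPase, the most by fitted log2 fold change, from 9.79 ± 8.01 to 1743 ± 182 normalized reads (log2 7.70 ± 0.52, adjusted p = 1.48e-06). Rragd, a Rag GTPase through which amino acids reach the growth kinase mTORC1, rose from 79.9 ± 15.1 to 3657 ± 178 (5.51 ± 0.19). Samd11 (7.32 ± 0.37), Ccdc155 (7.05 ± 0.62), the transcription factor Tox2 (5.75 ± 0.31) and Plcxd2 (5.68 ± 0.25) were the other largest rises. Prg2, the major basic protein of eosinophil granules, fell from 426 ± 112 to 3.34 ± 2.01 (−6.68 ± 0.37, adjusted p = 4.22e-07). Sema4c (−5.29 ± 0.21), the endothelial lipase Lipg (−5.05 ± 0.32), Trem1, a receptor that amplifies inflammation (−4.97 ± 0.31), Cxcl11 (−4.64 ± 0.28) and Serpina3g (−4.60 ± 0.42, uncertain because of near-identical paralogs) were the other largest falls.

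The fixed genes split under the inhibitor. Mthfd2 rose from 1056 ± 109 to 3906 ± 204 (log2 1.89 ± 0.16, adjusted p = 8.89e-06) and Shmt2 from 459 ± 126 to 1456 ± 171 (1.70 ± 0.22, adjusted p = 0.000174). Phgdh rose by 0.74 ± 0.24 (617 ± 101 against 379 ± 124, adjusted p = 0.0368), a call lost without LPS_NCT503 2 (0.62), LPS_NCT503 3 (0.75), LPS 1 (0.51) or LPS 2 (0.73). Psat1 (0.24 ± 0.19, adjusted p = 0.352) and Psph (0.24 ± 0.32, adjusted p = 0.597) did not pass. Il1b fell from 39556 ± 3651 to 2884 ± 111 (−3.77 ± 0.16, adjusted p = 1.76e-07), Il10 by 1.42 ± 0.27, Nos2 by 1.46 ± 0.32 and Il6 by 0.98 ± 0.23 on the log2 scale, whereas Ifnb1 rose from 19.8 ± 5.29 to 120 ± 44.9 (2.49 ± 0.34, adjusted p = 0.000234). Tnf, at 41259 ± 7637 against 29744 ± 5484, did not pass (0.47 ± 0.20, adjusted p = 0.0905). It was called under CPM scaling (log2 0.72), under quantile normalization (log2 0.79), by edgeR with a strict filter (log2 0.59) and without LPS_NCT503 2 (log2 0.61) or LPS 2 (log2 0.61). Arg1 (−1.26 ± 0.55, adjusted p = 0.102) was called only under quantile normalization (−1.59).

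The ATF4 target, aminoacyl-tRNA synthetase, ribosome biogenesis, heat shock and NRF2 target lists were called higher with the preset correlation, though no list passes with an estimated one. Of 25 ATF4 targets of the amino acid response 22 rose and 0 fell (median 1.88, adjusted p = 5.48e-13, and adjusted p = 0.185 with an estimated correlation). Examples are the stress cytokine Gdf15 (4.62), the pseudokinase Trib3 (3.32), the asparagine synthetase Asns (2.89) and the arginine transporter Slc7a1 (2.68). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 rose and 2, Farsa and Wars, fell, with 15 and 4 adjusted over the list alone (median 1.28, adjusted p = 6.71e-05, and adjusted p = 0.172 with an estimated correlation). Yars (1.89) and Mars (1.86) were among those that rose. Of 20 ribosome biogenesis genes 9 rose and 1 fell (median 0.33, adjusted p = 0.00745, and adjusted p = 0.465 with an estimated correlation). The nucleolar proteins Gnl3 (2.88) and Ncl (2.06) rose, and the call is lost without LPS_NCT503 2 (adjusted p = 0.0934, range 0.00233 to 0.465). Of 15 cytosolic heat shock genes 9 rose (median 0.66, adjusted p = 0.000655, and adjusted p = 0.378 with an estimated correlation). They included Hspa1a (2.85) and Hsph1 (2.45). Of 26 NRF2 targets and glutathione genes 12 rose and 5 fell (median 0.34, adjusted p = 0.0221, and adjusted p = 0.608 with an estimated correlation). The glutathione synthesis enzyme Gclc (2.45) and Srxn1 (2.12) rose. The NRF2 call is lost without LPS 1 (adjusted p = 0.122) or LPS_NCT503 2 (0.0882, range 0.00379 to 0.608). The serine synthesis and one-carbon list had 10 of 24 genes higher and 4 lower and missed the threshold (median 0.45, adjusted p = 0.0505). The result crosses it without LPS 3 (0.0162), without LPS_NCT503 1 (0.0250), by fry (0.0272), with the replicate number as a block (0.0425), with a pseudocount of 0.1 (0.0444), without a filter (0.0457) and under TMM (0.0490), within a range of 0.0162 to 0.573. The mitochondrial serine carrier Sfxn1 (2.35) rose and Aldh1l1 (−2.33) fell.

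Cholesterol synthesis fell further than any other metabolic list. Of its 24 genes 20 fell (median −2.05, adjusted p = 5.30e-13, and adjusted p = 0.0795 with an estimated correlation). These included the sterol enzymes Cyp51 (−3.82), Fdft1 (−3.40) and Msmo1 (−3.10). Insig1, which retains the SREBP precursors in the endoplasmic reticulum, rose. Of 30 respiratory chain genes 10 fell (median −0.40, adjusted p = 0.000201, and adjusted p = 0.573 with an estimated correlation). These included the electron carrier Cycs (−1.59). The self-contained fry test of the respiratory chain list gave an adjusted p of 0.0687. Over 14 alternatives of the list test, fry among them, the range was 6.51e-06 to 0.573. Glycolysis (7 of 30 higher, 5 lower, adjusted p = 0.940) and the tricarboxylic acid cycle (4 of 23 higher, 3 lower, adjusted p = 0.940) were not called.

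Called lower were 8 immune lists, each with members that rose or did not pass, while class II antigen presentation and alternative activation were not called. Of 22 feedback regulators of Toll-like receptor signalling 14 fell, 16 adjusted over the list alone (median −0.82, adjusted p = 1.36e-06, and adjusted p = 0.454 with an estimated correlation). Examples are Socs1 (−3.44), Dusp2 (−2.99) and Socs3 (−2.66). Of 31 interferon genes 20 fell, 21 adjusted over the list alone, among them Isg20 (−2.62), while Ifnb1 itself rose (median −0.96, adjusted p = 1.36e-06, adjusted p = 0.556 with an estimated correlation, and 0.0643 by fry, range 1.36e-09 to 0.556). Of 15 class I antigen presentation genes 12 fell, 13 with 1 higher adjusted over the list alone (median −1.27, adjusted p = 2.72e-06, and adjusted p = 0.454 with an estimated correlation). These included the immunoproteasome subunit Psmb10 (−2.19) and Tap2 (−1.85). Of 15 effectors 11 fell and 1 rose, 11 and 2 adjusted over the list alone (median −1.14, adjusted p = 1.46e-05, and adjusted p = 0.185 with an estimated correlation). Lcn2 (−3.33) and Saa3 (−2.70) fell and Ptgs2 rose. Of 17 chemokines 10 fell and 2 rose, with 10 lower and 4 higher adjusted over the list alone (median −2.28, adjusted p = 0.000674, and adjusted p = 0.465 with an estimated correlation). The monocyte attractants Ccl7 (−3.92) and Ccl2 (−2.57) fell and the neutrophil attractants Cxcl2 (2.51) and Cxcl1 rose. Of 17 cytokines 8 fell and 4 rose, with 9 and 5 adjusted over the list alone (median −0.81, adjusted p = 0.0215, and adjusted p = 0.454 with an estimated correlation). Il1b, Csf3 (−2.62) and Il1a (−2.09) fell, and Tnfsf15 (2.61) and Csf1 (1.13) rose.

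Of 12 inflammasome components 6 fell with NCT503 and 2 rose (median −0.60, adjusted p = 0.0116, and adjusted p = 0.465 with an estimated correlation). Txnip (−4.03) and the adaptor Pycard (−1.63) fell and Nlrp1b rose. Of 21 Toll-like receptor pathway components 9 fell and 3 rose, with 9 and 4 adjusted over the list alone (median −0.36, adjusted p = 0.0211, and adjusted p = 0.573 with an estimated correlation). The adaptor Myd88 (−2.55) and Cd14 (−2.38) fell, and Ticam1, Traf3 and Traf6 rose. Without LPS_NCT503 2 the cytokine (adjusted p = 0.0934, range 0.00294 to 0.454), inflammasome (0.0580, range 0.00382 to 0.465) and Toll-like receptor pathway (0.154, range 0.00436 to 0.573) calls are lost. Of 18 macrophage identity genes 12 fell, 13 adjusted over the list alone (median −0.82, adjusted p = 1.51e-05, and adjusted p = 0.185 with an estimated correlation). Among these were the lineage factor Spi1 (−1.83) and the Fc receptor Fcgr1 (−2.75).

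Lists of granulocyte, basophil and T and natural killer cell markers were called lower, and those of B cells, dendritic cells and erythroid cells were not. Of 14 neutrophil and granulocyte markers 12 fell (median −2.98, adjusted p = 1.92e-08, and adjusted p = 0.312 with an estimated correlation). Examples are the calprotectin subunits S100a9 (−4.44) and S100a8 (−3.52). All 8 mast cell and basophil markers fell (median −2.55, adjusted p = 9.83e-07, and adjusted p = 0.264 with an estimated correlation). These included Prss34 (−4.33) and Mcpt8 (−3.14). Of 12 T and natural killer cell markers 8 fell, 8 with 1 higher adjusted over the list alone (median −1.75, adjusted p = 0.00159, and adjusted p = 0.498 with an estimated correlation). Nkg7 (−2.38) was among them, and Gzma had 3 reads with NCT503 against 61 without. Scaled by the size factors, its ratio was 0.0406 (95% counting interval 0.00815 to 0.124, which leaves out the spread between libraries). Relative to their mean over all libraries, the median granulocyte marker stood between −2.40 and −1.60 in the 3 LPS_NCT503 libraries, between 0.55 and 1.56 in the LPS libraries and between 0.87 and 1.41 in the control libraries. Fibroblast and stromal markers were not called (2 of 12 higher, 3 lower, adjusted p = 0.775, with a median of 0.17, a mean of −0.27 and a test direction of lower).

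The other lists did not pass: osteoclast markers (1 of 9 higher, 3 lower, adjusted p = 0.155), cell cycle (4 of 30 and 9, or 5 and 9 adjusted over the list alone, 0.166), endoplasmic reticulum chaperones (4 of 20 and 7, 0.216), B cell markers (0 of 6 and 2, 0.338), fatty acid metabolism (7 of 25 and 9, or 8 and 10 adjusted over the list alone, 0.555), dendritic cell markers (0 of 8, 0.775), histone methylation (4 of 18 and 4, or 5 and 4 adjusted over the list alone, 0.876) and p53 targets (7 of 23 and 6) and erythroid markers (0 of 5), both at 0.940. At 0.313 were class II antigen presentation (1 of 12 higher, 3 lower), lysosome (9 of 32 and 3, or 9 and 4 adjusted over the list alone) and alternative activation (3 of 13 and 6, or 4 and 7 adjusted over the list alone). Median, mean and test differ in sign for histone methylation (−0.08, 0.02, lower), p53 targets (0.01, 0.06, lower) and glycolysis (−0.21, 0.11, lower).

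**Figure D2:**
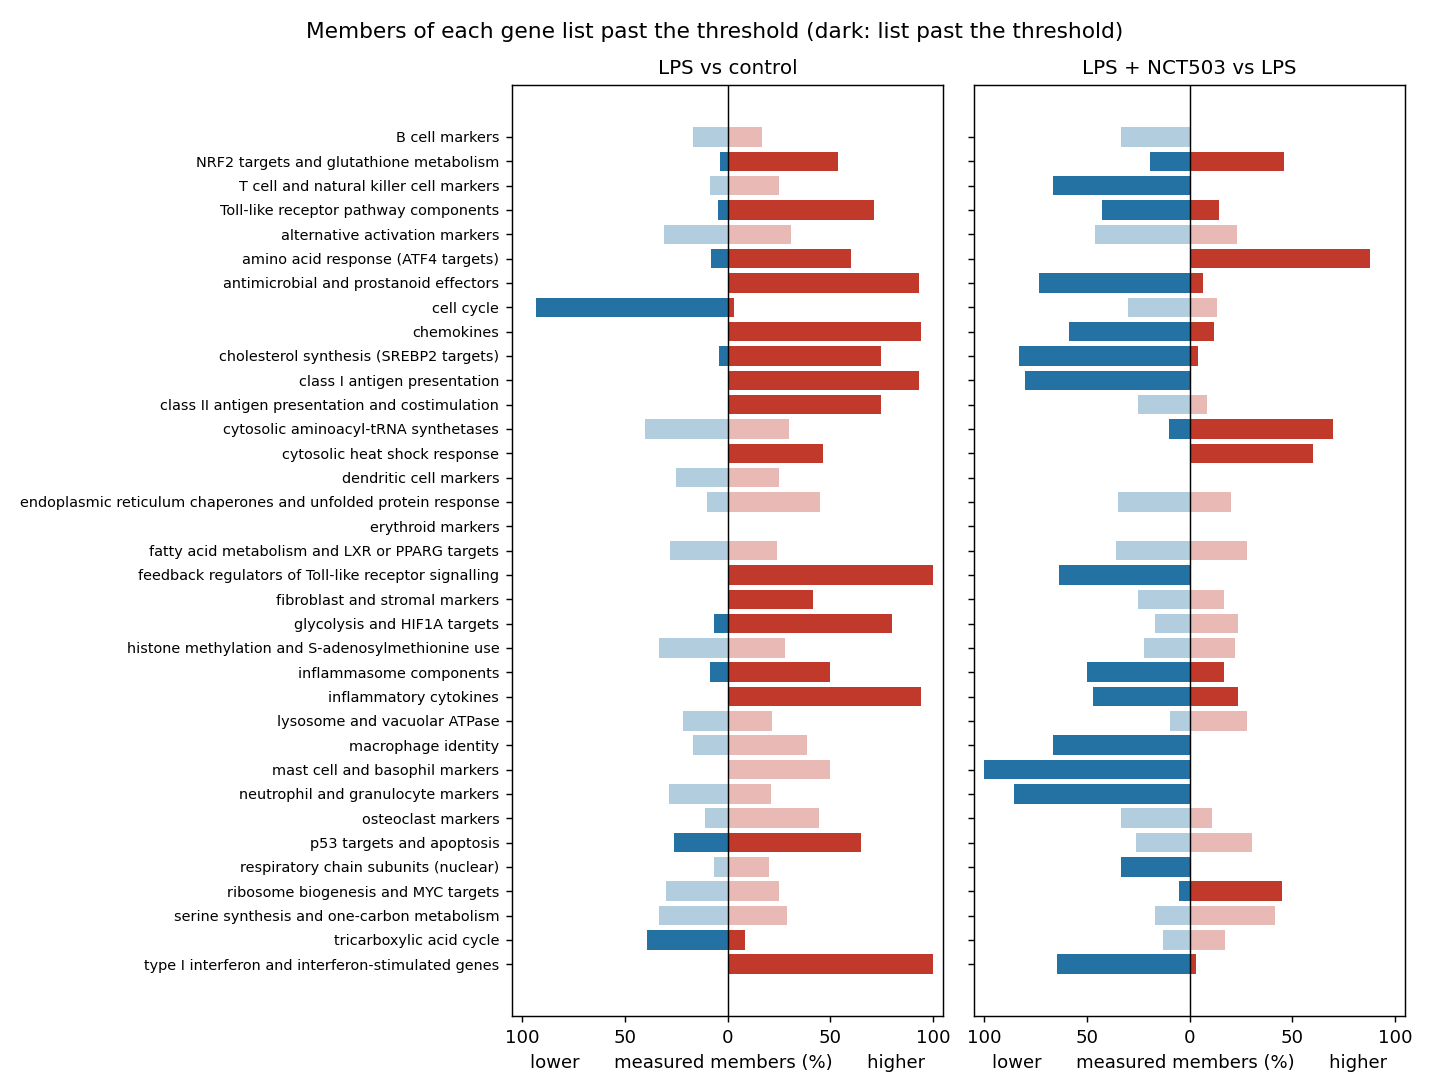
Percent of the measured members of each of the 35 gene lists that passed higher (right) or lower (left) with LPS against control and with LPS and NCT503 against LPS, dark bars marking lists past an adjusted p of 0.05. Of these lists 18 were called with LPS, where the inflammasome, heat shock and class II medians turn sign under another scaling, and 19 with NCT503, where no called list turns.

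Across all genes tested with LPS and NCT503 against LPS, 6449 of 19795 passed, 3351 higher and 3098 lower, and 4373 of them changed at least 2-fold, while the authors' deposited comparison passes 6193 (3134 higher, 3059 lower). Under CPM scaling, which shifts the median of all genes by 0.22 (quantile normalization −0.10), 4405 rose and 2137 fell, and without LPS_NCT503 3 the number that passed was 4334. Of the 35 lists 19 were called, 5 higher and 14 lower, and none of them passes with an estimated correlation, where the smallest adjusted p is 0.0795. Another grouping of the same 6 libraries also called 19 lists, but it too keeps part of the treatment difference and does not measure chance calls.

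Against untreated cells, where single genes alone were tested, the largest rise in macrophages given LPS with NCT503 was that of Cxcl2. It rose from 16.7 ± 8.73 to 59904 ± 11368 normalized reads (log2 11.82 ± 0.30, adjusted p = 1.50e-08), followed by Ptgs2 (11.13 ± 0.49), Cxcl1 (11.01 ± 0.28), Nos2 (10.01 ± 0.45), Il12b, a subunit of the cytokines that drive T helper responses (9.09 ± 0.51), and Ptges (8.64 ± 0.18). The 6 largest falls were Prg2 (−6.03 ± 0.36), Sesn1 (−5.48 ± 0.18) and 4 genes of neutrophil granules and cytosol, Mpo (−5.40 ± 0.60), Elane (−5.29 ± 0.44), Prtn3 (−4.83 ± 0.55) and S100a9 (−4.61 ± 0.38). Mpo stood at 25.5, 97.8 and 17.3 normalized reads in the LPS_NCT503 libraries, and at 1578 ± 497 in control.

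Mthfd2 rose by 2.68 ± 0.14 in this comparison, Phgdh by 1.79 ± 0.18, Shmt2 by 1.45 ± 0.16 and Psat1 by 1.28 ± 0.18, while Psph did not pass (0.15 ± 0.31, adjusted p = 0.735). Tnf (8.42 ± 0.19), Il6 (8.43 ± 0.36), Il1b (7.70 ± 0.22), Ifnb1 (4.80 ± 0.41) and Il10 (2.17 ± 0.28) were above untreated cells, and Arg1 (−0.33 ± 0.60, adjusted p = 0.696) was not past the test. In all, 8061 of 19930 genes passed, 4134 higher and 3927 lower, and under CPM scaling, with the median of all genes shifted by −0.41 (quantile normalization −0.14), 2452 rose and 6568 fell.

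NCT503 moved many LPS-responsive genes in the direction opposite to that of LPS. No library had NCT503 without LPS, so an effect of the inhibitor apart from LPS cannot be separated from a changed LPS response. Of 4089 genes raised by LPS, 1818 (44.5%) fell with NCT503, among them Il1b, Il10, Nos2, Socs3, Lcn2 and Cd14, and 422 rose further, among them Cxcl2, Ptgs2, Ifnb1 and Mthfd2. Of 4110 genes lowered by LPS and tested in both comparisons, 1427 (34.7%) rose with NCT503 and 218 fell further. Under CPM scaling 948 of 2092 raised genes fell and 2784 of 8269 lowered genes rose with NCT503. In all 3245 genes moved in opposite directions, where independent lists of these sizes would share 667 and 696, and 640 moved in the same direction, where they would share 693 and 671. Because the comparisons share the LPS libraries with opposite sign, chance in those libraries alone makes the fold changes oppose each other. In 20 simulations with no effect their covariance across genes was −0.12 against an observed −0.70, but the correlation (−0.58, observed −0.46) and the percent of genes with opposite sign (68.3%, observed 67.3%) were at least as large without any effect. With different LPS libraries in the 2 comparisons, 1 in one and 2 in the other, 1180 to 2271 genes moved in opposite directions, where independent lists would share 434 to 910, and 184 to 481 in the same direction, where they would share 430 to 910. The correlation was then −0.39 to −0.30.

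**Figure D3:**
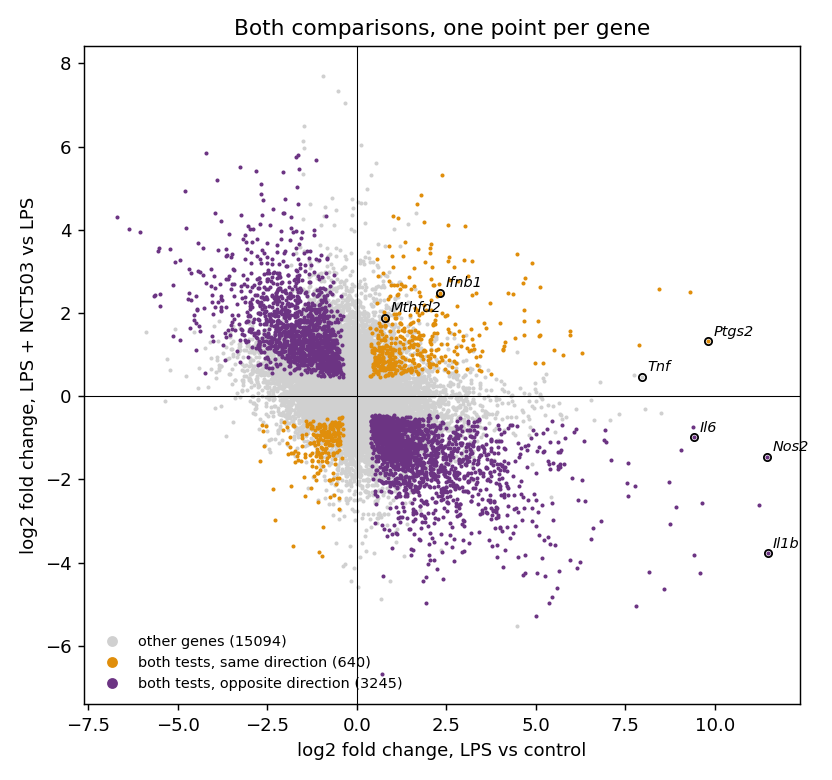
Log2 fold change of LPS against control (horizontal) and of LPS with NCT503 against LPS (vertical), 1 point per gene of the 18979 tested in both. Genes past the test in both comparisons are coloured, 3245 with opposite and 640 with the same direction.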

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

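Chosen after seeing the data were edgeR with its standard filter, the mean of at least 10 normalized reads, CPM scaling, leaving out control 1 and LPS_NCT503 2 together, and different LPS libraries in the 2 comparisons, while all other alternatives were planned. No deposited comparison of LPS with NCT503 against control was among the files used, so that alternative has no value there.

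The total of called genes in each comparison was within 1.5 times its main value under all alternatives except edgeR with at least 10 CPM in every library of a group. There, by construction, fewer genes were tested, and 5215 (2499 higher, 2716 lower) were called with LPS, 4018 (2055 and 1963) with NCT503 against LPS and 5062 (2458 and 2604) with NCT503 against control. By construction a 2-fold minimum also left fewer: 2710 higher with LPS, 1883 lower with NCT503 against LPS, 2562 lower with NCT503 against control, and 1884 genes of opposite direction. CPM scaling turned the balance to 2092 higher and 8536 lower with LPS and to 2452 and 6568 with NCT503 against control. With 1 library left out, 6432 (without control 2) to 8553 genes were called with LPS, 4334 (without LPS_NCT503 3) to 7304 with NCT503 against LPS, 5808 (without control 2) to 9141 with NCT503 against control, and 10738 there without control 1 and LPS_NCT503 2. Genes raised by NCT503 ranged from 2213 (without LPS_NCT503 3) to 3748, and genes of opposite direction from 2266 (without LPS 3) to 3485. With replicate numbers as a block 9714, 8186 and 8098 genes were called, and 4316 of opposite direction. With different LPS libraries in the 2 comparisons, and so fewer in each, the number of opposite direction was 2088, 2271 and 2084 with only LPS 1, 2 or 3 against control and 1180, 1615 and 1406 with only LPS 1, 2 or 3 against NCT503. The correlation across genes of libraries with the same number, after the group means were removed, was between −0.21 and 0.37, and genes are not independent replicates. With NCT503 against LPS, replicates 1 (0.37) and 2 (0.31) correlated best with their own number and replicate 3 (−0.11) did not. Elsewhere only replicate 1 with LPS against control did (0.17). Shared batches with NCT503 against LPS are therefore not decided. Numbers were not taken as pairs, since the labels give only a number.

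Of the single-gene values under alternatives, 3500 kept direction and side of the threshold, 7 lost a call, 8 gained one and 8 turned sign. The turns were all in genes not called. Psph turned to 0.22 with LPS under quantile normalization and ranged from −0.20 to 0.026 with a library left out. Psph also ranged from −0.10 to 0.59 with NCT503 against LPS and from −0.19 to 0.50 against control, where CPM scaling gave −0.30. Arg1 against control ranged from −0.86 to 0.06 with 1 library left out, and was 0.34 without control 1 and LPS_NCT503 2. The cause was not tested.

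Of the list values under alternatives, 836 kept direction and side, 48 lost a call, 23 gained one and 73 turned direction, each of these in a list not called. With an estimated correlation 6 lists were called with LPS and 0 with NCT503 against LPS. By fry the stromal list with LPS was not called (0.111) and osteoclast markers were called in both comparisons (0.000623 and 0.000703). With a mean of at least 10 reads the inflammasome (0.103) and tricarboxylic acid cycle (0.0591) calls with LPS and the Toll-like receptor pathway call with NCT503 (0.0621) were lost, and the block brought mast cell markers with LPS to 0.0368 and the serine list with NCT503 to 0.0425. The cause was not tested.

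Adjusted p-values of lists not called whose direction turned with LPS were as follows. Without a filter: alternative activation, histone methylation, B cell and erythroid markers 0.979. Under TMM: alternative activation, lysosome, B cell and erythroid markers 0.983. With a pseudocount of 0.1: histone methylation 0.994. With the block: B cell and erythroid markers 0.981. With a mean of at least 10: lysosome 0.976, B cell markers 0.908, erythroid markers 0.941. Under CPM scaling: alternative activation 0.767, endoplasmic reticulum chaperones 0.917, respiratory chain 0.0556, lysosome 0.0103, neutrophil markers 0.901, erythroid markers 0.688. By fry: alternative activation and fatty acid metabolism 0.475, tRNA synthetases 0.801, lysosome 0.813, histone methylation 0.948, neutrophil markers 0.651. With a library left out: alternative activation and erythroid markers 0.834 to 0.995, serine synthesis 0.554 to 0.997, fatty acid metabolism 0.710 to 0.995, lysosome 0.573 to 0.979, histone methylation 0.917 to 0.995, neutrophil markers 0.389 to 0.995, B cell markers 0.554 to 0.995, dendritic cell markers 0.768 to 0.995.

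With NCT503 against LPS they were, without a filter, erythroid markers 0.917. With the block: glycolysis 0.967, erythroid markers 0.984. With a mean of at least 10: glycolysis and p53 targets 0.952, erythroid markers 0.811. Under CPM scaling: glycolysis 0.785, p53 targets and erythroid markers 0.885, histone methylation 0.933. By fry: glycolysis 0.353, histone methylation 0.634. With a library left out: glycolysis 0.716 to 0.986, tricarboxylic acid cycle 0.760 to 0.988, p53 targets 0.791 to 0.988, stromal markers 0.492 to 0.951, erythroid markers 0.602 to 0.988.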

Other observations

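The tests of LPS_NCT503 2 and of the blood cell markers, and the genes and name families given here, were chosen after the values were seen. The tests of other splits of the libraries were planned. Those of the zinc finger genes were set before they were run. The zinc finger family itself came from a scan of these data, where 1 of 15 transcription factor families was called with NCT503 against LPS. Single genes chosen in this way do not stand for a group. The metallothioneins Mt1 (log2 4.48 ± 0.20, from 1410 ± 323 to 31031 ± 3020 normalized reads, adjusted p = 1.92e-07) and Mt2 (5.32 ± 0.26), which bind zinc and copper, and the zinc exporter Slc30a1 (3.44 ± 0.21) rose in LPS with NCT503 against LPS, while with LPS alone none of the 3 passed (−0.57 ± 0.22, 0.40 ± 0.35 and −0.15 ± 0.16). Flcn, a regulator of the Rag GTPases (1.84 ± 0.18), the transcription factor Tfeb (1.12 ± 0.20) and the proton pump subunit Atp6v0d2 (2.20 ± 0.18) rose with NCT503, although the lysosome list was not called (9 of 32 higher, 3 lower, median 0.04, adjusted p = 0.313). LPS had lowered these 3 (Flcn −1.27 ± 0.15, Tfeb −1.59 ± 0.20, Atp6v0d2 −1.83 ± 0.17). The heme oxygenase Hmox1 rose in both comparisons (1.53 ± 0.17 with LPS, 1.35 ± 0.15 with NCT503), and Ifng rose with LPS (8.74 ± 0.40) and fell with NCT503 (−3.07 ± 0.52), beside the T and natural killer cell markers.

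Genes grouped by name stem, the letters before the first digit, were also tested as families. A stem also takes in genes named after a family, such as those of binding proteins, so the labels are approximate. With NCT503, 8 of 10 genes of the stem Psmb (proteasome core, adjusted p = 0.000547), 6 of 10 of Casp (caspases and genes named after them, 0.00529), 7 of 11 of Irf (interferon regulatory factors and genes named after them, 0.00666) and 9 of 16 of Ifi (interferon-induced, 0.0160) fell and 0 rose. By contrast 8 of 13 Hspa heat shock genes rose (0.0201). None of these turned under any scaling tested and none passes with an estimated correlation. With LPS, 9 of 10 Psmb (0.000244) and 11 of 14 Psmd (0.00112) proteasome genes rose, and 22 of 34 kinesins (Kif, 0.000408), 21 of 37 centrosomal proteins (Cep, 0.00104) and 7 of 10 genes of the stem Mcm (replication helicase genes and genes named after them, 0.0222) fell, again with no turn, and none passes with an estimated correlation. The scan called 19 of 178 name families with LPS and 11 of 183 with NCT503, of which these are examples. With LPS the medians of 4 called families turn under CPM scaling: Irf (0.59 to −0.11), Ppp (0.45 to −0.22), Ube (0.40 to −0.30) and Stx (0.57 to −0.07). The Psmd median kept its sign there but shrank from 0.74 to 0.03. The naming rule was narrowed after a look at its output. Immunoglobulin variable genes, measured at low levels, fell in 20 of 75 cases with NCT503 (median −1.29, adjusted p = 4.99e-07, and adjusted p = 0.940 with an estimated correlation). In control 1, 100 of 10870 genes stood over 4-fold above the other control libraries, among them the endothelial genes Cdh5 (362 against 30.8 and 24.8 normalized reads) and Plvap (877 against 85.4 and 48.9) and the stromal and matrix genes Col3a1 (2358 against 388 and 562), Sparc (3659 against 655 and 1044), Postn (513 against 91.0 and 127) and Pdgfrb (290 against 70.0 and 71.3).

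C2H2 zinc finger genes were called as a family with the preset correlation but not with an estimated one, and many members did not pass: with NCT503 130 of 456 rose and 41 fell (median 0.58, adjusted p = 0.00365, and adjusted p = 0.892 with an estimated correlation), and with LPS 58 of 468 rose and 197 fell (median −0.69, adjusted p = 0.00198, and adjusted p = 0.492 with an estimated correlation), in the same directions under each scaling. The trend of each library on gene length was then removed. The rise with NCT503 kept its call in camera of limma with the preset correlation (unadjusted p = 0.000608 and median 0.40, from 0.000244 and 0.58 before). The family median also lay at percentile 100 of 10000 lists matched on length and expression level (median 0.23, highest 0.44). In these fits length and level account for part of the median. Both tests treat genes as nearly independent, so they cannot tell what lies behind a shift that these genes share. Other technical sources were not tested, and an effect of the inhibitor stays open, untested.

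Granulocyte, basophil and T and natural killer cell markers fell together with NCT503: of 34 measured 28 fell and 0 rose. The median stromal marker lay 3.14 log2 units above the median granulocyte marker, beyond the SD of 1.67 of the stromal markers. That SD is between markers and is no error of the median. The stromal markers were split, 2 of 12 higher and 3 lower (mean −0.27), with Thy1 (−3.54), Pdgfrb (−2.59) and Pdgfra (−1.83) lower and Postn (2.22) higher. Whether all other cell types had a lower share alike is therefore not decided. Fewer granulocytes, basophils and T and natural killer cells and lower expression in them cannot be told apart, since either gives the 28 falls and no cell counts are in the files used. Which cells the marker reads came from, macrophages included, was not measured. With LPS against control these markers were split. Of 14 granulocyte markers 3 rose and 4 fell, of 8 mast cell and basophil markers 4 rose, and of 12 T and natural killer cell markers 3 rose and 1 fell.

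In LPS_NCT503 2, 77 of 10803 genes stood over 4-fold apart from both other libraries of its group, 32 higher and 45 lower, while in the 7 libraries other than this and control 1 the number was 0 to 6. For the 45 lower genes, dilution by RNA of other cells is argued against, since it would need 82.0% of such RNA for their median of −2.47. The median macrophage identity gene lay 0.085 above the other libraries (SD 0.58). These 45 genes were also chosen for a difference over 4-fold. A minor cell type that was scarcer in this library would leave macrophage genes unmoved, and stays open. The median T and natural killer cell marker stood at −1.91 there, against −0.40 and −0.80 in the other libraries of the group. For the 32 higher genes, RNA of stromal cells and other sources cannot be told apart: 9 of 12 stromal markers were higher, but their median lay 0.725 above the other 2 libraries (SD 0.774), a rise too small to decide, and the 32 genes, chosen for a difference over 4-fold, are no fair measure beside it. Relative to all libraries the median stromal marker stood at 1.15, the highest of the 9, and at 0.08 and 0.59 in the other 2. The ribosomal gene Rps2 had 934 normalized reads against 19361 and 20034, but its sum with near-identical copies differed by only −0.040 (Rps2-ps10 had 15683 against 509 and 445), so reads of Rps2 may have moved to copies, as a sequence difference between genomes could bring about. Of the 77 genes 29 had another of them, with a different name stem, within 1 Mb, against a mean of 9.24 and a maximum of 26 in 10000 random draws (one-sided permutation p = 1e-04, the smallest they can give), which is consistent with linked stretches of another strain, though shared regulation of neighbours stays open. Examples are Slfn8 (99.9 against 4685 and 3322), Gdpd3 (1710 against 22.4 and 19.5) and Itgax (9371 against 561 and 548), and no other explanation was tested.

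The splits of 6 libraries number 10 per comparison, the real one included, too few for a share under 0.05. For genes the real splits gave 8355, 6449 and 8061 and the highest other split 0 in each comparison, so 1 of 10 splits reached the real number. For lists the real split with LPS gave 18 and the highest other 17 (1 of 10 as large), and with NCT503 the real split gave 19 and another split also 19 (2 of 10 as large). The other splits mix the treatments unevenly in each group. Part of the treatment difference stays between the groups and can call lists. The rest adds to the spread within groups and lowers the gene calls. These splits therefore cannot show how many genes or lists would be called by chance.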
